A study of Homo sapiens with 4 samples.

How the data were processed

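RNA was measured in 4 libraries of NUGC3 cells, 2 of wild-type cells and 2 of cells with a MYC knockdown, with the group and replicate of each taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a standard Illumina protocol. How MYC was knocked down is not given in the sources used here, nor is whether the libraries were stranded or selected for poly(A). Per the submitters' processing notes, STAR and RSEM were used. Their versions, the genome build and the annotation are not given in the sources used here.

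The values are FPKM per gene as deposited by the authors, rounded to 2 decimals. The unit was inferred from the values: the columns sum to between 674328 and 739335 and not to 1 fixed total as TPM would, and low values come in steps that shrink with transcript length. TPM with some rows left out cannot be fully excluded. The table has 344810 rows, of which 53777 are Ensembl genes (20269 protein-coding) and 291033 are other noncoding entries. The Ensembl rows were used, because the other entries can overlap them. In 29 Ensembl rows the symbol had been turned into a date, and these genes were not named. Where the table splits reads between near-identical genes, such as ribosomal protein genes and their pseudogenes, single values are uncertain.

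FPKM does not keep the depth. The values of genes with 1 transcript of 400 to 1500 bases were searched for steps. If the larger of the steps found is 1 fragment, the libraries held about 28.5, 22.9, 21.4 and 22.0 (each times 1e+06) fragments (wild type replicates 1 and 2, MYC knockdown replicates 1 and 2). The smaller step would be 1 fragment shared between 2 entries. Read counts were not recovered, so no count test was run, and no counting interval is given.

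Before the data were examined, the test, the gene lists, the rule for named genes and most alternatives were fixed. The design foresaw a count test for counts and limma for TPM or FPKM, and the latter applied. Genes with at least 1 FPKM in at least 2 libraries (12953) were tested on log2(FPKM + 1) with limma 3.58.1 (lmFit, eBayes with a mean trend) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 changes are knockdown minus wild type on that scale, which understates the change of low genes. Groups were said not to overlap where both values of a group lay above both of the other. The share of 33.3% given for chance assumes that both groups vary alike, and is too low where 1 group varies more. No batch is given in the labels.

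The 34 gene lists were tested with limma's camera (preset correlation 0.01, and also an estimated correlation) and fry, adjusted over the lists. The form with an estimated correlation rests on the fit's 2 residual degrees of freedom, so it has little power here. Members were matched by symbol or through a table of older symbols. The lists and their results are all given with the comparison.

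The named genes were MYC; the 6 genes with the largest log2 change in each direction among those past the threshold with a mean of at least 5 FPKM, groups that do not overlap and a symbol that names a gene; the 2 members with the smallest p past the threshold of each list camera called; and the 1 such member of each other list. At 0.05 this rule named 1 gene, MYC. It was therefore applied at an adjusted p of 0.10, which named 55 genes and was chosen after the values were seen. Some genes that the rule names are not reported here. The interferon-stimulated genes named were chosen after their values were seen.

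The fit was tested on simulated libraries, in 20 sets of 12953 genes for the comparison of MYC knockdown with wild type. Their spread was modelled on these data but drawn alike for both groups and independently for each gene. In the data the median SD on the log2 scale was 0.05 in wild type and 0.14 in the knockdown, so the counts need not carry over. Of 200 genes changed by 0.5, 1 and 2 on the log2 scale, 0, 73.9 and 187 were recovered on average at 0.05, with 0.1, 4.7 and 9.8 false calls. At 0.10, 0, 137 and 192 were recovered. With 1300 genes changed by 1, 960.5 were recovered at 0.05 with 46.8 false calls, since the share recovered depends on how many genes change. Camera called 0 lists on average where nothing was changed. The simulated genes were independent, so this does not show how often camera calls unchanged lists whose members are correlated. In the data the estimated correlation was 0.46 for the known MYC-induced genes and −0.02 for lysosome and autophagy genes.

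Alternatives were the filter on low values, the pseudocount (0.1), a block for the replicate number, each library left out, a test against a fold of 1.5, a threshold of 0.01, an estimated correlation, and list members shared with another list left out. Added after seeing the data were the threshold of 0.10, protein-coding rows alone, all rows, and 3 scalings (median of ratios, quantile, equal column sums). Transcript length and GC content came from GENCODE release 29 on GRCh38, and the position of MYC from the same release. It is not known whether the authors used that build. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and drawn with matplotlib 3.10.9.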

Results

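Gene expression was measured by RNA sequencing in NUGC3, an established human cell line from a stomach cancer. Of the 4 libraries, 2 came from wild-type cells and 2 from cells with a knockdown of MYC, a transcription factor that drives growth and ribosome production. The question was how the RNA profile of the line differs when MYC is knocked down. The deposited FPKM of the 4 libraries summed to 739335, 730732, 708058 and 674328, in the order wild type replicates 1 and 2 and MYC knockdown replicates 1 and 2. The depth is not given, but steps in the low values put wild type replicate 2 at 80.3% and MYC knockdown replicate 2 at 77.2% of the depth of wild type replicate 1, with MYC knockdown replicate 1 slightly below these. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

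MYC itself (ENSG00000136997; chromosome 8, 127735434 to 127741434, plus strand, in GENCODE release 29 on GRCh38) was only slightly lower in the knockdown libraries. It stood at 82.9 and 82.0 FPKM in the wild-type libraries and at 65.0 and 75.8 FPKM in the knockdown libraries, or 82.4 ± 0.615 against 70.4 ± 7.66 FPKM (SD, n = 2 per group). Both knockdown values lay below both wild-type values, as the labels say. The log2 change was −0.23 with a standard error of 0.10, which did not pass the test (limma adjusted p = 0.237). Without MYC knockdown replicate 2 the change was −0.34 and passed the threshold. That fit held 1 knockdown library and took its spread from the close wild-type pair, so its pass says little. The change was −0.12 without MYC knockdown replicate 1 and −0.13 with equal column sums, and neither passed.

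As lists, genes of the translation machinery, known MYC-induced genes and genes of several biosynthetic pathways were lower in the knockdown libraries, and lysosome and autophagy genes were higher. Limma camera called these lists with a preset correlation, and 0 of the 34 lists with an estimated correlation, where the smallest adjusted p was 0.229. Ribosomal protein genes showed the most uniform difference, with a median log2 change of −0.44 over 78 genes. The known MYC-induced genes lay at a median of −0.42 and the lysosome and autophagy genes at 0.50. Interferon-stimulated genes were far higher in MYC knockdown replicate 1 than in MYC knockdown replicate 2. For single genes, limma with Benjamini-Hochberg adjustment called 0 of 12953 genes at 0.05, the smallest adjusted p being 0.0556, shared by 147 genes. At an unadjusted p under 0.05 there were 3354 genes, of which 1866 were higher and 1488 lower in the knockdown, where chance gives 648. At an adjusted p under 0.10, a threshold added after the count at 0.05 had been seen, limma called 1349 genes, 713 higher and 636 lower. With every library scaled to the same FPKM sum, that count was 2220 genes, 1640 higher and 580 lower, and the median log2 change over all genes moved from 0.04 to 0.12. The groups did not overlap for 4324 genes that were higher and 3262 that were lower in the knockdown, 58.6% of the genes tested. Chance gives 33.3% if both groups vary alike. The median SD on the log2 scale was 0.05 in wild type and 0.14 in the knockdown, which raises the share expected without a difference.

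The wild-type libraries lay much closer together than the knockdown libraries. The median absolute log2 difference between libraries was 0.08 for the wild-type pair and 0.20 for the knockdown pair, and 0.24 for each pair across the groups. The first principal component held 54.9% of the variance and separated the groups. The second held 33.0% and separated MYC knockdown replicate 1 from MYC knockdown replicate 2. The count of calls moved with the library left out. Without MYC knockdown replicate 1 or 2, where the spread rests on the wild-type pair, limma called 3688 and 3680 genes at 0.05. Without wild type replicate 1 or 2, where it rests on the knockdown pair, limma called 0 and 1 genes. In those fits the lone library was assumed to vary like the other group.

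Among genes with an adjusted p under 0.10, those with the largest values above wild type included KYNU (ENSG00000115919), kynureninase of tryptophan breakdown, at 144 ± 29.9 FPKM in the knockdown against 41.6 ± 1.73 FPKM in wild type (SD, n = 2). CYP4V2 (ENSG00000145476), a fatty acid hydroxylase, stood at 13.8 ± 1.18 against 3.63 ± 0.0636 FPKM. LAMA3 (ENSG00000053747), a laminin chain of epithelial basement membranes, and CD82 (ENSG00000085117), a tetraspanin, had log2 changes of 1.59 and 1.59. ANO1 (ENSG00000131620), a calcium-activated chloride channel, and SMOC1 (ENSG00000198732), a secreted calcium-binding protein, had log2 changes of 1.57 and 1.55. The limma adjusted p of these 6 genes lay between 0.0556 and 0.0841, so none passed 0.05.

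PLAC8 (ENSG00000145287), a small cysteine-rich protein, was at 24.8 ± 7.10 FPKM in the knockdown against 138 ± 2.34 FPKM in wild type (SD, n = 2), a log2 change of −2.46. With a pseudocount of 0.1 it was −2.50, behind RELN at −2.74 and the cyclin CCND2 at −2.83. RELN (ENSG00000189056), the secreted glycoprotein reelin, and EBI3 (ENSG00000105246), a cytokine subunit, had log2 changes of −2.21 and −1.95. SCD (ENSG00000099194), the desaturase that makes monounsaturated fatty acids, and EGR1 (ENSG00000120738), an immediate early transcription factor, had log2 changes of −1.87 and −1.87. NDRG1 (ENSG00000104419), known as a gene that MYC proteins repress, stood at 9.71 ± 4.89 against 34.5 ± 0.622 FPKM, a log2 change of −1.81. The limma adjusted p of these 6 genes lay between 0.0556 and 0.0709.

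**Figure D1:**
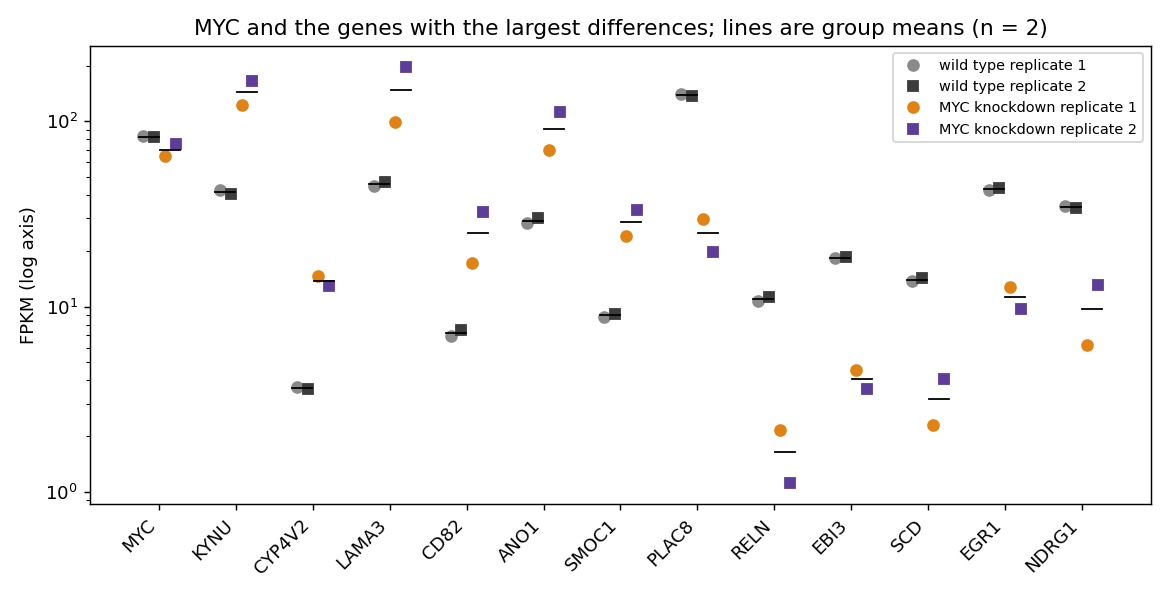
FPKM on a log axis of MYC and of the genes with the largest changes among those at an adjusted p under 0.10, with 1 point per library and a line at each group's mean (n = 2). The wild-type points nearly coincide in every gene, MYC is at 65.0 and 75.8 FPKM in the knockdown libraries, and PLAC8 goes from a mean of 138 to 24.8 FPKM.

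Cytosolic ribosomal protein genes were lower as a list in both knockdown libraries, at a median log2 difference from the wild-type mean of −0.42 in MYC knockdown replicate 1 and −0.46 in MYC knockdown replicate 2. RPL6 stood at 1032 ± 4.87 FPKM in the knockdown against 1773 ± 9.72 FPKM in wild type (SD, n = 2), and RPS23 at 890 ± 8.14 against 1434 ± 30.2 FPKM. Of 78 members, 76 had both knockdown values below both wild-type values and 0 had them above. For both directions together, chance gives 33.3% and all genes tested gave 58.6%. At 0.05, 0 members passed over all genes tested and 72 did when adjusted over the list alone, all lower. The limma camera test called the list (adjusted p = 1.9e-34), a call lost at adjusted p = 0.240 with an estimated correlation. With quantile normalization the list's median was −0.16, still lower.

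Known MYC-induced genes were lower as a list, at a median of −0.34 in MYC knockdown replicate 1 and −0.52 in MYC knockdown replicate 2. Of 57 members, 47 were lower and 3 higher where groups did not overlap (33.3% by chance, 58.6% over all genes tested). HK2, the hexokinase of the first step of glycolysis, stood at 11.4 ± 0.509 FPKM against 29.4 ± 0.389 FPKM in wild type, and NPM1, a nucleolar histone chaperone, at 618 ± 5.82 against 1019 ± 28.4 FPKM (SD, n = 2). Over all genes 0 passed 0.05, and adjusted over the list alone 35 were lower and 1 higher. The list was called by limma camera (adjusted p = 9.4e-17), and not with an estimated correlation (adjusted p = 0.485 with an estimated correlation). Genes of ribosome biogenesis and RNA polymerases I and III were lower too, at a median of −0.28 over 74 genes, among them BOP1, a ribosome assembly factor, at 29.5 ± 1.39 against 59.9 ± 1.51 FPKM in wild type (SD, n = 2) and DDX21, a nucleolar helicase, at a log2 change of −0.59. Of these 74 genes, 0 passed over all genes and 25 adjusted over the list alone, all lower (limma camera adjusted p = 4.0e-13; adjusted p = 0.492 with an estimated correlation). The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, had a median of −0.36 over 20 genes, with AARS at −0.55 and LARS at −0.52. In that list 0 passed over all genes and 14 adjusted over the list alone, all lower (limma camera adjusted p = 1.5e-08; adjusted p = 0.451 with an estimated correlation). Chaperones of the cytosol and mitochondria had a median of −0.32 over 28 genes, with HSPB1, a small heat shock protein, at −0.82 and PFDN2, a prefoldin subunit, at −0.51. Here 0 passed over all genes, and adjusted over the list alone 16 were lower and 1 higher (limma camera adjusted p = 3.0e-10; adjusted p = 0.270 with an estimated correlation).

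Metabolic lists were lower in the same way. Glycolysis and lactate export had a median of −0.49 over 22 genes, with LDHB, a lactate dehydrogenase subunit, at 283 ± 19.3 FPKM against 447 ± 6.20 FPKM in wild type (SD, n = 2) and HK2 at a log2 change of −1.30. Over all genes 0 passed 0.05, and adjusted over the list alone 14 were lower and 2 higher (limma camera adjusted p = 1.8e-07; adjusted p = 0.229 with an estimated correlation). Cholesterol synthesis and uptake had a median of −0.49 over 23 genes, with SQLE, squalene epoxidase, at −1.04 and SREBF2, the transcription factor that induces this pathway, at −1.09. In that list 0 passed over all genes and 13 adjusted over the list alone, all lower (limma camera adjusted p = 3.0e-10; adjusted p = 0.476 with an estimated correlation). Nucleotide synthesis had a median of −0.23 over 31 genes, −0.15 with equal column sums, with IMPDH2 of guanine nucleotide synthesis at −0.85 and PAICS of purine synthesis at −0.69. There 0 passed over all genes and 11 adjusted over the list alone, all lower (limma camera adjusted p = 1.6e-08; adjusted p = 0.229 with an estimated correlation). Amino acid starvation and ATF4 targets had a median of −0.32 over 29 genes, with DDIT4, an inhibitor of mTORC1 signalling, at −1.12 and PYCR1 of proline synthesis at −1.09. Of its members 0 passed over all genes and 13 adjusted over the list alone, all lower (limma camera adjusted p = 6.7e-08; adjusted p = 0.229 with an estimated correlation).

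Polyamine synthesis and turnover had a median of −0.27 over 15 genes, −0.18 with equal column sums, with ARG2, a mitochondrial arginase, at −1.30 and SMS, spermine synthase, at −0.42. Over all genes 0 passed and adjusted over the list alone 5 did, all lower (limma camera adjusted p = 8.7e-04; adjusted p = 0.300 with an estimated correlation). The list of mitochondrial ribosome, import and DNA maintenance had a median of −0.21 over 59 genes, −0.13 without MYC knockdown replicate 2 and −0.12 with equal column sums, with MRPL12 at −0.63 and TIMM13 at −0.60. Its counts were 0 over all genes and 9 adjusted over the list alone, all lower (limma camera adjusted p = 1.8e-09; adjusted p = 0.550 with an estimated correlation).

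Cell cycle and respiratory chain lists were lower by less, and 1 knockdown library decided these calls. G1 and S phase genes had a median of −0.13 over 45 genes, −0.04 with equal column sums, including CCND2, a D-type cyclin, at −1.63 and CDK6, its kinase partner, at −0.59, and adjusted over the list alone 3 were lower against 0 over all genes (limma camera adjusted p = 0.00254; adjusted p = 0.618 with an estimated correlation). G2 and M phase genes had a median of −0.09 over 45 genes, with MYBL2, a cell cycle transcription factor, at −0.59 and KIF20A, a mitotic kinesin, at −0.43, and adjusted over the list alone 1 was lower against 0 over all genes (limma camera adjusted p = 0.0226; adjusted p = 0.695 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes had a median of −0.08 over 56 genes, with CYCS, cytochrome c, at −0.68 and UQCRH of complex III at −0.50, and adjusted over the list alone 3 were lower against 0 over all genes (limma camera adjusted p = 0.00341; adjusted p = 0.695 with an estimated correlation). These 3 lists were no longer called without MYC knockdown replicate 2, at medians of −0.01, −0.05 and −0.0045, and were called without MYC knockdown replicate 1, at −0.23, −0.17 and −0.16. With equal column sums the medians of the G2 and M phase genes and of oxidative phosphorylation were 0.00042 and 0.01, on the other side of 0, and neither was called; with quantile normalization both calls were lost too, at −0.10 and −0.06.

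NF-kB targets and cytokines had a median of −0.20 over 25 genes, −0.10 with equal column sums, with the chemokine CCL20 at 178 ± 11.9 FPKM against 325 ± 9.40 FPKM and the cytokine IL1A at 473 ± 56.1 against 968 ± 4.90 FPKM (SD, n = 2). Over all genes 0 passed, and adjusted over the list alone 5 were lower and 1 higher (limma camera adjusted p = 0.0177; adjusted p = 0.420 with an estimated correlation). Its call was lost without MYC knockdown replicate 1, with quantile normalization and with a mean of at least 5 FPKM, at medians of −0.25, −0.22 and −0.14. The MYC network, partners and antagonists of MYC, had a median of −0.12 over 18 genes, with MXI1, a MYC antagonist, at −0.88, and 1 member passed adjusted over the list alone against 0 over all genes (limma camera adjusted p = 0.0429; adjusted p = 0.451 with an estimated correlation). Its call was lost without wild type replicate 1, wild type replicate 2 or MYC knockdown replicate 1, at medians of −0.13, −0.08 and −0.08, and with equal column sums, at −0.03.

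Lysosome and autophagy genes were higher as a list, at a median of 0.49 in MYC knockdown replicate 1 and 0.42 in MYC knockdown replicate 2. SQSTM1, the autophagy receptor p62, stood at 180 ± 10.9 FPKM against 104 ± 1.87 FPKM in wild type (SD, n = 2). Of 37 members, 26 were higher and 1 lower where groups did not overlap (33.3% by chance, 58.6% over all genes tested). Over all genes 0 passed 0.05 and adjusted over the list alone 21 did, all higher (limma camera adjusted p = 8.2e-09; adjusted p = 0.229 with an estimated correlation).

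Interferon-stimulated genes, which respond to virus or interferon, were high in 1 knockdown library. Their median log2 difference from the wild-type mean was 1.89 in MYC knockdown replicate 1 and 0.11 in MYC knockdown replicate 2, and 29 of 33 members were over 1 higher in the former against 0 in the latter. Both knockdown values lay above both wild-type values for 18 of 33 members and below them for 0, a share below the 58.6% of all genes tested whose groups did not overlap (33.3% by chance). IFI6 stood at 11.1 and 10.2 FPKM in wild type and at 375 and 11.6 FPKM in the knockdown libraries, and ISG15, a ubiquitin-like protein, at 53.9, 49.0, 308 and 57.1 FPKM. MX1, an antiviral GTPase, stood at 6.82, 5.47, 107 and 7.35 FPKM. Limma camera called the list higher (adjusted p = 7.9e-04, median 1.18; adjusted p = 0.695 with an estimated correlation), while 0 members passed 0.05 over all genes and 0 adjusted over the list alone. Without MYC knockdown replicate 1 the median was 0.08 and the call was lost (limma camera adjusted p = 0.640, against a range of 1.7e-18 to 0.695 over all alternatives).

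**Figure D2:**
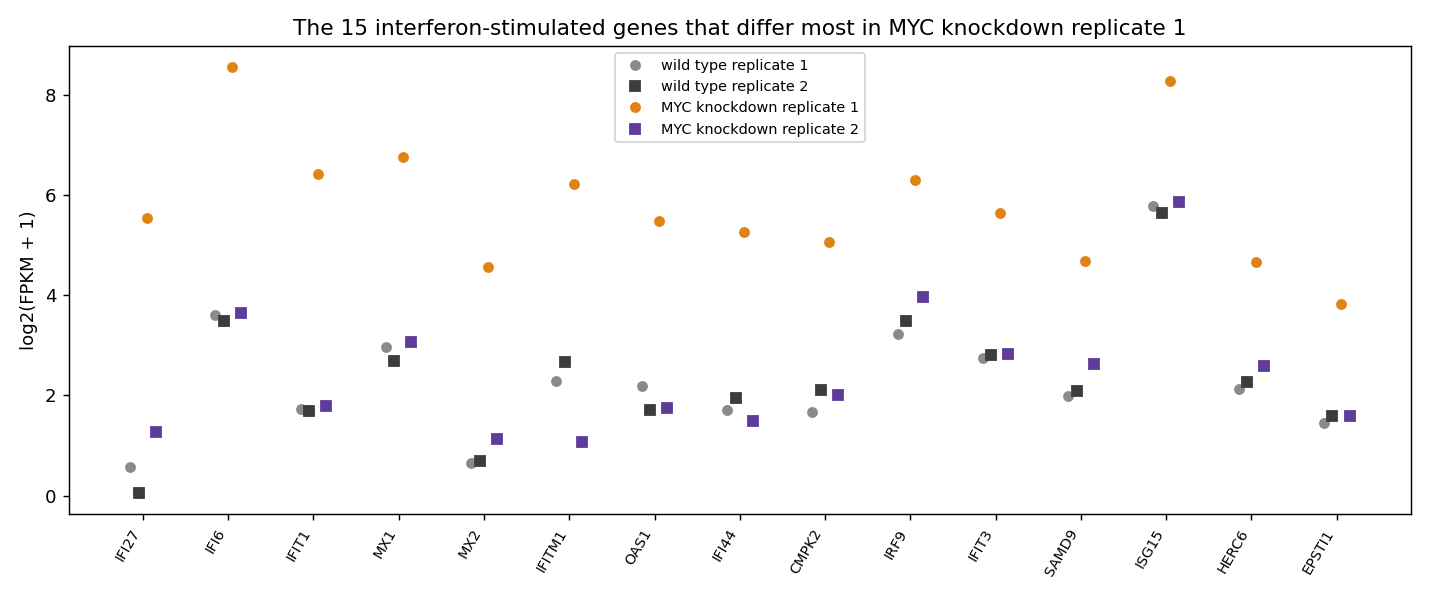
The log2(FPKM + 1) of the 15 interferon-stimulated genes with the largest difference of MYC knockdown replicate 1 from wild type, in that order, with 1 point per library. MYC knockdown replicate 1 is the highest point for each gene, and the medians over all 33 genes tested of MYC knockdown replicates 1 and 2 are 1.89 and 0.11 above the wild-type mean.

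The other 16 lists were not called by limma camera, and 0 of their members passed 0.05 over all genes. Mitochondrially encoded genes differed between the knockdown libraries, at a median of 0.10 in MYC knockdown replicate 1 and −0.51 in MYC knockdown replicate 2, and 0 of 13 passed adjusted over the list alone. The mitochondrial share of the summed FPKM was 9.62% and 8.99% in wild type and 10.3% and 7.75% in the knockdown. This list was called without wild type replicate 2 or MYC knockdown replicate 1, at medians of −0.23 and −0.51. Mesenchymal genes and matrix had a median of 0.24 over 25 genes with COL4A1, a basement membrane collagen, at −1.61, and adjusted over the list alone 1 was higher and 4 lower. Replication-dependent histones had a median of 0.29 over 13 genes with HIST2H2BE at 0.76 and 0 adjusted over the list alone. Without MYC knockdown replicate 1 both were called, at medians of 0.43 and 0.44. Antigen presentation and immune checkpoint ligands had a median of 0.24 over 25 genes with PDCD1LG2, a ligand of the receptor PD-1, at 0.83, and 1 was higher and 1 lower adjusted over the list alone. Immediate early genes had a median of −0.05 over 20 genes, 0.04 with equal column sums, and 3 were higher and 3 lower adjusted over the list alone. Without MYC knockdown replicate 2 both were called, at medians of 0.38 and −0.31, and without MYC knockdown replicate 1 both medians changed sign, to −0.03 and 0.01. Over all alternatives the medians ranged from −0.51 to 0.10 for the mitochondrially encoded genes, from −0.03 to 0.43 for the mesenchymal genes, from 0.12 to 0.51 for the histones, from −0.03 to 0.38 for antigen presentation and from −0.31 to 0.04 for the immediate early genes. The lowest values of the mesenchymal genes and the histones were those without MYC knockdown replicate 2.

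The medians of the remaining lists were given with their lowest and highest values over all alternatives in brackets. The p53 targets had a median of 0.18 (0.08 to 0.27) over 22 genes, the lowest without MYC knockdown replicate 1, with FUCA1, a lysosomal fucosidase, at 0.97, and 2 were higher adjusted over the list alone. Stomach and intestine lineage genes had a median of 0.30 (0.01 to 0.61) over 10 genes, the lowest without a filter on low values and the highest with a mean of at least 5 FPKM, with SOX9 at 0.61, and 3 were higher and 1 lower adjusted over the list alone. The BCL2 family and apoptosis list had a median of 0.09 (0.02 to 0.18) over 20 genes, the lowest without a filter and the highest with equal column sums, with BIRC2, an inhibitor of apoptosis, at 0.52, and 1 was higher adjusted over the list alone. WNT pathway targets had a median of −0.0046 (−0.18 to 0.25) over 6 genes, the lowest without MYC knockdown replicate 2 and the highest with a mean of at least 5 FPKM, with NOTUM at −0.76 and 0 adjusted over the list alone. In 5 lists the median, mean and test differed in sign, and in 4 of these, the CDK inhibitors excepted, so did the medians with 1 library left out. CDK inhibitors and growth arrest genes repressed by MYC had a median of 0.22 (0.11 to 0.32), the lowest without MYC knockdown replicate 2, a mean of −0.01 and a test direction of higher over 21 genes. GADD45A, a growth arrest gene, was lower there at −0.95, and 3 members were higher and 2 lower adjusted over the list alone. Hypoxia and HIF1 targets had a median of 0.05 (−0.02 to 0.15), the lowest without MYC knockdown replicate 1 and the highest with equal column sums, and a mean of −0.12 with a test direction of lower over 17 genes, and 3 were lower adjusted over the list alone. Epithelial genes had a median of −0.04 (−0.08 to 0.08), the lowest with median-of-ratios scaling and the highest without MYC knockdown replicate 2, a mean of 0.11 and a test direction of higher over 25 genes. KRT19, a keratin, was at 0.74 there, and 5 were higher and 1 lower adjusted over the list alone. Neighbours of MYC on chromosome 8 had a median of 0.01 (−0.03 to 0.10), the lowest with median-of-ratios scaling and the highest with equal column sums, a mean of −0.01 and a test direction of lower over 16 genes, with 1 lower adjusted over the list alone. Receptor tyrosine kinases and RAS pathway genes had a median of 0.01 (−0.03 to 0.10), at the same scalings, a mean of 0.01 and a test direction of lower over 27 genes. DDR1, a collagen receptor, was at 0.45 there, and 0 passed adjusted over the list alone. Of markers of other cell types, only 1 leukocyte gene and 2 fibroblast or endothelial genes reached the filter, with 1 and 1 higher adjusted over the list alone and medians of 0.56 (0.01 to 0.77) and 0.22 (−0.25 to 0.55). Without wild type replicate 1 the former was 0.34, and without MYC knockdown replicate 1 the latter was −0.11.

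**Figure D3:**
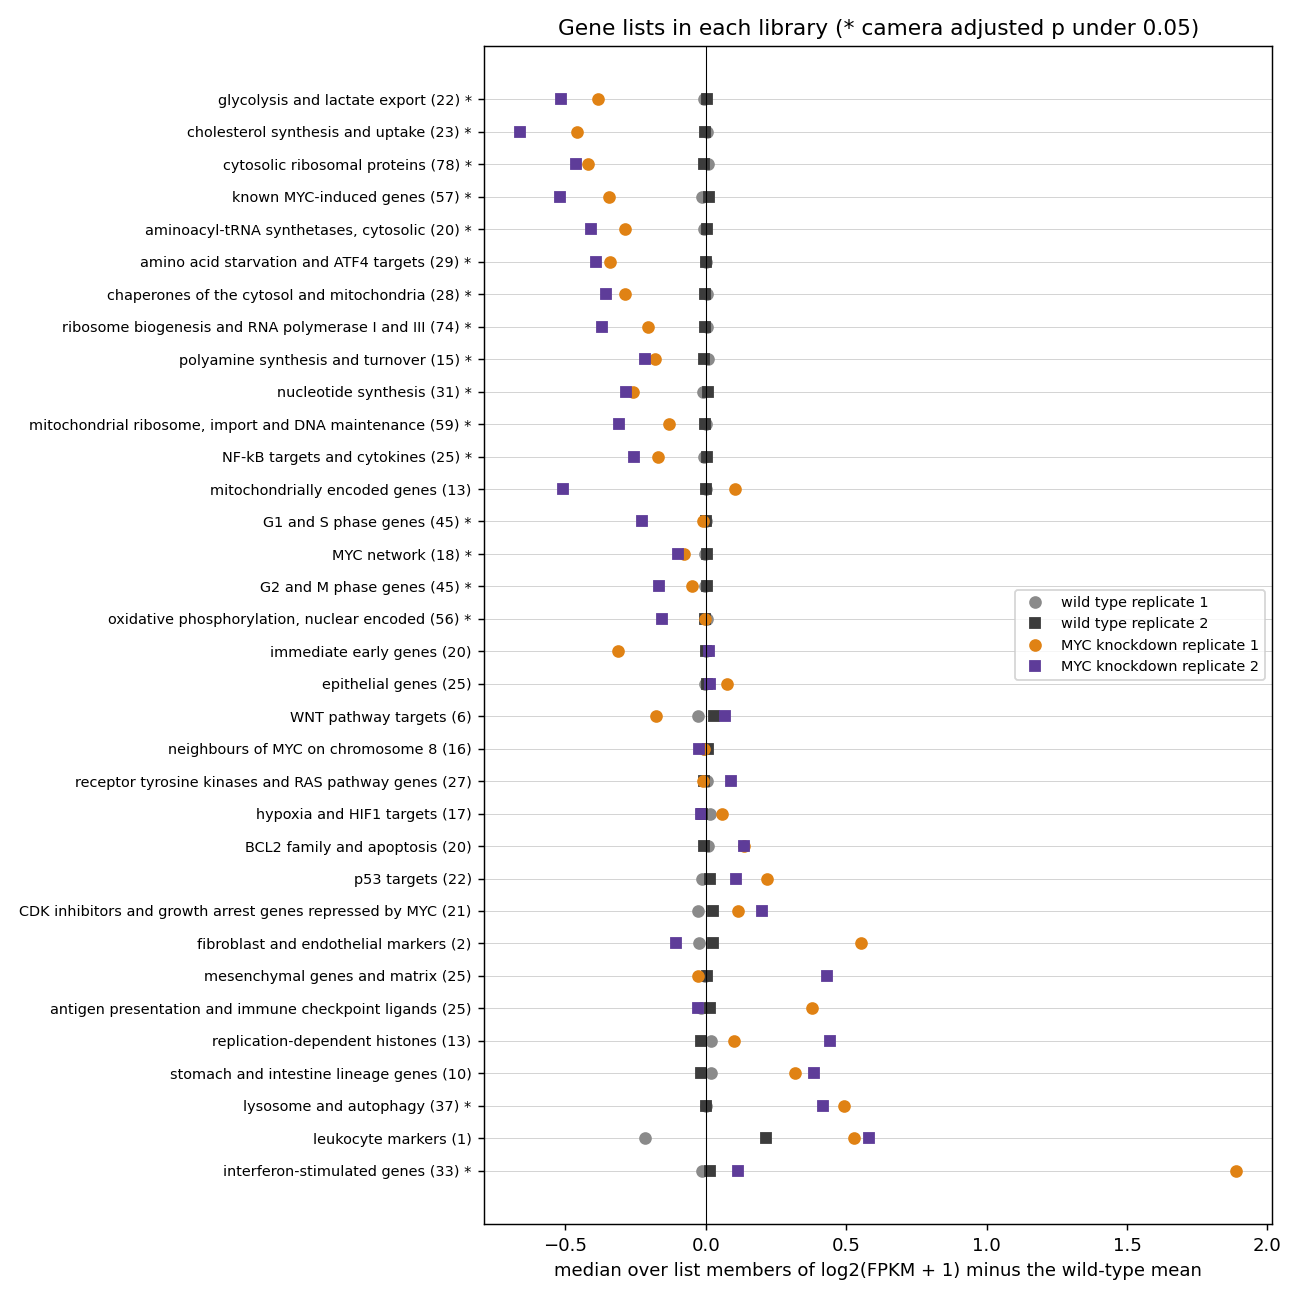
Median over the tested members of each gene list of log2(FPKM + 1) minus the wild-type mean, with 1 point per library and the number of members in brackets. Ribosomal proteins lie at −0.42 and −0.46 in the knockdown libraries, and the interferon-stimulated genes lie apart at 1.89 in MYC knockdown replicate 1.

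Across the 34 lists, limma camera with a preset correlation called 18 at 0.05, 16 lower and 2 higher. With an estimated correlation camera called 0, the smallest adjusted p being 0.229. That form of the test rests on 2 residual degrees of freedom, so it decides little either way. Lysosome and autophagy genes, at an estimated correlation of −0.02, lost their call, as did the known MYC-induced genes, at 0.46. The limma test fry, which asks whether the genes of a list move one way on balance, called 17 lists, among them 10 of the 18. Of the 18, it did not call the known MYC-induced genes or the aminoacyl-tRNA synthetases (fry adjusted p = 0.054 for each). Nor did it call ribosome biogenesis (fry adjusted p = 0.074), the mitochondrial ribosome list, G1 and S phase, G2 and M phase, oxidative phosphorylation or interferon-stimulated genes. Outside the 18 it called p53 targets, immediate early, lineage, BCL2 family, hypoxia and epithelial genes and the neighbours of MYC.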

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

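The tests of the interferon response, of the slight change in MYC, and of scaling for the ribosomal proteins were chosen after the results were seen.

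Noncoding entries outside the Ensembl annotation, which the comparison did not use, held 8.91% of the summed FPKM in the knockdown libraries on average, against 8.51% and 8.47% in the wild-type libraries. Of 1206 such entries with a mean of at least 5 FPKM, 28 were at least 2 times higher in both knockdown libraries than in both wild-type libraries, and 22 were at least 2 times lower. Of 6807 such entries tested, limma called 0 at an adjusted p under 0.05 and 907 had an unadjusted p under 0.05.

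Interferon-stimulated genes were far higher in MYC knockdown replicate 1 than in the other 3 libraries. Leukocytes in that library are argued against, because the summed leukocyte markers exceeded their wild-type mean by 5.89 FPKM where the summed interferon list exceeded its own by 2451 FPKM. A shift of the whole library is argued against too, since 0% of 10000 random lists matched on mean expression reached the list's median of 1.89, the highest reaching 0.38. The known MYC-induced genes had a median of −0.34 in that library relative to wild type. This argues against a library like the wild-type ones under a knockdown label. It cannot tell a knockdown from a wild-type culture in which the response itself lowered these genes. A response to a delivery reagent, a knockdown construct or an infection in 1 culture stays open and untested, as does MYC knockdown itself. In MYC knockdown replicate 2 the list's median was 0.11, above 91.6% of matched random lists. The random lists held unrelated genes, while the interferon genes moved together (estimated correlation 0.995), so that percentage gives no level of chance. The list's summed FPKM in that library, 748, lay below both wild-type sums of 839 and 849.

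Cytosolic ribosomal protein genes were lower in both knockdown libraries. Transcript length and GC content are argued against as the whole cause, because the median was −0.47 (interquartile range −0.52 to −0.40) after removing their trend, against −0.44 before. Reads moved to ribosomal protein pseudogenes are argued against, since the summed FPKM of 855 pseudogene rows was lower as well, by a knockdown minus wild-type difference of −424 FPKM. Under 3 other scalings the highest median was −0.16, so the choice among these scalings is argued against as the whole cause. All 3 are relative to the RNA measured in each library, so they cannot show a change in RNA per cell. As a hypothesis, lower MYC activity may lower these RNAs, as the design's groups would have it, but a slower growth of these cultures was not tested.

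MYC RNA was only slightly lower although its known induced genes were lower. MYC and these genes did not rank the knockdown libraries alike. In MYC knockdown replicates 1 and 2, MYC differed from the wild-type mean by −0.34 and −0.12. The median of the known MYC-induced genes differed from it by −0.34 and −0.52. A swap between a wild-type and a knockdown library is argued against, because 50 of the 57 known MYC-induced genes had groups that did not overlap, 87.7% where chance gives 33.3% and all genes tested gave 58.6%. Under 3 other scalings the lowest MYC change was −0.27, which argues against the choice among these scalings. They cannot show a change in RNA per cell, which stays untested here too. A knockdown that acts mainly on the protein, a loss of knockdown by the time of harvest, or RNA made from a construct may leave the RNA near the wild-type level; these stay open and untested.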

How the results depend on the processing

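The threshold of 0.10, the rows used and the 3 scalings were chosen after the data were seen; the other alternatives were fixed before. The smallest adjusted p of the comparison lay just above 0.05, so small changes of the genes tested or of the scaling moved the count of 0 genes. It was 310 (131 higher, 179 lower) with a mean of at least 5 FPKM, 314 (100 and 214) with median-of-ratios scaling, 385 (170 and 215) with protein-coding genes alone and 1349 at a threshold of 0.10. It stayed at 0 without a filter, with a pseudocount of 0.1, with all rows, with quantile normalization, with equal column sums, at a threshold of 0.01 and against a fold of 1.5. Leaving out 1 library gave 0 to 3688 genes, high without MYC knockdown replicate 1 or 2 (3688 and 3680), where the spread rests on the close wild-type pair with 1 residual degree of freedom.

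The count of 1349 genes at 0.10 became 0 without a filter, where 24879 genes were tested, 588 with all rows and 2220 (1640 higher, 580 lower) with equal column sums. It was 0 and 1 without wild type replicate 1 or 2 and 5443 and 5425 without MYC knockdown replicate 1 or 2, and the cause of the changes with scaling was not tested. MYC and the genes named by the rule changed direction under none of the alternatives run. The MYC change lay between −0.34 and −0.12 when 1 library was left out. It passed the threshold only without MYC knockdown replicate 2, in a fit with 1 knockdown library. The count of 18 lists called became 0 with an estimated correlation and was 15 to 18 under the other alternatives. The lists that lost their call under the latter were the MYC network, NF-kB targets, oxidative phosphorylation, G1 and S phase, G2 and M phase and interferon-stimulated genes; the other 12 of the 18 kept it. The MYC network also lost it with shared members left out, with a mean of at least 5 FPKM and with the replicate block.

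Same-numbered libraries did not deviate together from their group means (correlation across genes −0.0059, genes not being independent). With 1 pair of differences, this cannot show whether they shared a culture, day or batch, which the labels do not give. With the replicate number as a block, 0 genes were called at 0.05, 723 at 0.10 and 17 lists, and MYC stayed at −0.23. The alternatives for counts and for isoform rows were not run, because the table holds FPKM with 1 row per gene. In simulated libraries with 200 genes changed by 0.5 on the log2 scale, 0 were recovered at 0.05; this bounds nothing where more genes change, and PFDN2, at −0.51, passed 0.05 with a mean of at least 5 FPKM.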

Other observations

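The comparison of the knockdown libraries with each other was chosen after the values were seen, and the test of RNA polymerase III transcripts before their values were seen.

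The knockdown libraries differed by over 1 on the log2 scale in 418 genes, 222 higher in MYC knockdown replicate 1 and 196 higher in MYC knockdown replicate 2, against 138 genes for the wild-type pair. Besides interferon-stimulated genes, those with the widest differences included the following, also chosen after their values were seen. MMP1, a collagenase, stood at 35.0 and 34.2 FPKM in wild type, 32.1 FPKM in MYC knockdown replicate 1 and 264 FPKM in MYC knockdown replicate 2. In the same order, ANGPT2, a ligand of the endothelial receptor TIE2, stood at 1.07, 1.10, 4.90 and 49.1 FPKM, and TNC, the matrix protein tenascin, at 5.89, 5.07, 9.39 and 46.1 FPKM. CXCL5, a chemokine, stood at 188, 188, 155 and 628 FPKM, AREG, a ligand of the EGF receptor, at 10.2, 7.69, 20.4 and 72.0 FPKM, and PTHLH, the parathyroid hormone-related peptide, at 23.5, 23.4, 41.4 and 133 FPKM. MMP9, a gelatinase, stood at 10.4, 10.3, 0.54 and 6.04 FPKM, and SERPINB2, a plasminogen activator inhibitor, at 51.6, 53.5, 9.62 and 35.5 FPKM. With 1 library on each side, these differences have no replicate check.

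RN7SL2, singled out after its values were seen, a gene of the signal recognition particle RNA that RNA polymerase III makes, stood at 3203 and 4181 FPKM in wild type and at 1513 and 1698 FPKM in the knockdown, a log2 change of −1.19 (limma adjusted p = 0.0566). A hypothesis was that transcripts of this polymerase, which MYC is known to activate, were lower together. Of 17 others listed, 3 passed the filter: RN7SK, RMRP and RPPH1, at −1.98, −1.35 and −1.85. Their median log2 change of −1.85 is the value of RPPH1 itself. All 3 were lower, which goes with the hypothesis, but none of the 3 passed 0.05 in limma. Reads of RN7SL2 are uncertain because of its near-identical copy RN7SL1, at −0.92. In the order used above, RN7SK stood at 12.3, 4.77, 1.67 and 0.85 FPKM and RMRP at 16.5, 7.71, 5.31 and 2.74 FPKM. RPPH1 stood at 3.85, 6.07, 0 and 1.65 FPKM. The wild-type libraries thus also differed, and several of these values are near the floor. The step search put the fragment length at 280 or 290 bases. Whether these RNAs are long enough beside it for a steady FPKM was not tested, so their lower values do not decide the hypothesis. These RNAs lack poly(A) tails, and a lower yield of such RNAs may also lower them. The replication-dependent histones, a class whose transcripts mostly lack them too, had a median of 0.29. Of 36 histones listed, 13 were tested, and whether their transcripts in these cells lack the tails is not known. The histones therefore do not decide the point.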
